A study of Mus musculus with 2 samples.

How the data were processed

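H3K4me3, trimethylation of lysine 4 of histone H3, a mark of active and poised promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the embryonic facial prominence of mice at embryonic day 14.5 (E14.5). Per the labels, the mice were of strain B6NTac;B6NCrl/Lap, and each of the 2 biological replicates was a separate pool of embryos of both sexes, 24 embryos for replicate 1 and 34 for replicate 2. Both replicates belong to 1 group, and no second condition was analysed here, so the comparisons made are those between the replicates and those between sets of genes or peaks within the samples.

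The deposited files used here are peak lists on mm10. Per the text files deposited with the samples, peaks were called once on each replicate and once on both replicates together (the pooled list), each call with further files as input, and a replicated list was derived from the pooled list and both replicates' lists. The peak caller, its version and threshold and the rule behind the replicated list are not given in the sources used here. Of the 23612 replicated peaks used, 22110 overlapped peaks of both replicates' lists by at least 50% of either peak, 1426 did so in 1 list and 76 in none. How reads from near-identical copies were treated is not given either, so calls at globin, histone, ribosomal protein and chemoreceptor genes are uncertain. Peak starts and ends are deposited as 0-based BED positions (other unit) and are printed 1-based. Column 7 of each deposited list was read as the fold enrichment of the peak over the control, a ratio, from the order of the columns in the format the authors named and from its range. Columns 8 and 9 of the deposited lists were read as −log10 p and −log10 q of the peak; column 8 was used only to rank peaks within each replicate's list. Fold enrichment and q are the authors' values of single peaks and were used to describe, rank or filter peaks within their own list. The lists reach weak peaks, with q up to 0.58 in replicate 1, 0.57 in replicate 2 and 0.36 in the replicated list. Peaks with −log10 q under 5 made up 25.9%, 26.6% and 5.36% of these lists. A gene called marked can thus rest on a weak peak. Fold enrichment was also correlated across the replicates' lists, compared between shared and single-list peaks of the same list, and used to match random gene lists by decile. The lists hold no read counts, so the depth of the libraries is unknown, and no interval that needs it is given.

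Peaks on chromosomes 1 to 19, X and Y were kept, and peaks on unplaced scaffolds were left out (17 in replicate 1, 15 in replicate 2, 10 in the replicated list). The reference was GRCm38, the assembly that mm10 names, with the GENCODE M21 annotation; all peak ends lay within its chromosome lengths. A peak counted as shared where the overlap was at least 50% of either peak, and bedtools 2.31.1 gave the same number of shared peaks as the Python code used for the other steps. Chance overlap came from 100 random placements of the peaks within their chromosomes. A promoter was 1 kb either side of any transcription start site (TSS) of a protein-coding transcript, and a gene with a peak there was called marked. Peaks at most 1 kb apart were joined into domains, and a gene's domain width was that of the widest domain over any of its promoters. Its fold enrichment was likewise the highest among its promoter peaks. Genes with more annotated TSSs thus had more chances of a wide domain, and no random list was matched on the number of TSSs. Where a domain covered promoters of several genes, it counted for each of them. Peaks over 5 kb from any annotated TSS were called distal. Promoters were classed by the observed over expected CpG ratio within 500 bp of the most 5' TSS, high at 0.6 and above and low below 0.35.

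Before the data were examined, 26 gene lists and a rule for the genes to name were fixed. The lists held cranial mesenchyme and neural crest regulators, orofacial cleft, osteoblast, chondrocyte, tooth germ, epithelium and palate genes, markers of other cell types or organs, signalling, Hox, housekeeping, ribosomal protein, histone, imprinted and chemoreceptor genes. Of the 34 symbols fixed for the cleft list 33 matched a protein-coding gene (Pvrl1, an older symbol of Nectin1, which was also listed, did not), of the 18 erythroid symbols 17 (not Ahsp) and of the 22 imprinted symbols 20 (H19 and Meg3 are noncoding); the members counted are those matched. The share of marked members was compared with all other protein-coding genes by Fisher's exact test, two-sided. The median domain width of the marked members was compared with 10000 random lists of as many marked genes, with a two-sided p from the percentile; this is a permutation of list membership among marked genes and is called a permutation test in the text. Both sets of p were adjusted by the Benjamini-Hochberg method over the 26 lists, with calls at 0.05. These tests are across genes in these samples; genes are not replicates, neighbouring genes can share a domain, and lists share members, so a p-value describes how far a list stands apart here. Shared and single-list peaks were compared by a permutation test of medians with 10000 resamples, across peaks. Values of both replicates are given as mean ± SD with n = 2 where they are averaged.

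The genes named are the 10 with the widest replicated domains, 1 gene per domain; per list the 2 marked members with the widest domains and the first 2 unmarked members in alphabetical order; the 3 promoters per replicate with the highest enrichment among those marked in 1 replicate's list only; the 3 distal peaks with the highest fold enrichment; and 15 facial regulators fixed by name. Any other gene named was chosen after its values were seen, as the text says. Alternatives fixed before the data were examined were a stricter threshold (−log10 q of at least 5), the top 20000 peaks per list, other overlap rules, promoter windows, joining distances and TSS choices, the pooled list or 1 replicate's list in place of the replicated one, random lists matched on the decile of fold enrichment, and a background without chemoreceptors. Added later were matching on CpG ratio or CpG number, leaving members of the cranial list out of the other lists, and a stricter replicated list. CpG ratio and CpG number were taken around the most 5' TSS and matched by decile, while a gene's peak or domain can lie at another TSS.

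The list tests were checked on simulated lists of 20 genes. With widths doubled or halved, 100% of lists had p under 0.05, and with no change 3.00% did. For shares, 92.0% of raised, 99.0% of lowered and 2.00% of unchanged lists did. These lists were drawn at random, so the check does not cover lists whose members share domains or are alike in CpG content. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.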

Results

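H3K4me3 was mapped in facial prominences, the embryonic tissue that forms the jaws, palate, nose and teeth, from 2 pools of E14.5 mouse embryos. The list of replicate 1 held 27830 peaks over 37.3 Mb and that of replicate 2 held 29331 peaks over 38.6 Mb (28580.5 ± 1061 peaks, SD, n = 2). The authors' replicated list held 23612 peaks over 40.6 Mb with a median width of 1538 bp. The number of reads behind each list is unknown. The design implies 3 questions, namely which genes carried the mark at their promoters, how wide the marked domains were, and how far the replicates shared their peaks.

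Of 21853 protein-coding genes, 14496 (66.3%) had a replicated H3K4me3 peak at a promoter. The share was 66.5% in replicate 1's own list and 66.6% in replicate 2's (66.6% ± 0.042, SD, n = 2). The mark followed the CpG ratio at the gene's most 5' TSS. Of the 10185 genes with a high ratio 98.5% were marked, of the 3729 intermediate ones 81.1% and of the 7939 low ones 18.1%. Between replicates these shares had an SD of 0.134 percentage points or less. A gene counted as marked with a peak at any of its TSSs, so the peak can lie at a TSS other than the one classed.

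Every listed regulator of the facial mesenchyme carried the mark. All 40 cranial mesenchyme and neural crest regulators had a replicated promoter peak, as did all 33 orofacial cleft genes, 28 tooth germ regulators, 22 palate genes and 20 limb regulators. These shares of 100% compared with about 66.3% of other protein-coding genes (Fisher's exact test, adjusted p = 5.8e-07, 9.6e-06, 5.0e-05, 3.1e-04 and 8.5e-04). The differences of 33.7 percentage points were smaller against random lists matched on the CpG ratio, a comparison chosen after seeing the data. They were then 9.23, 13.4, 19.04, 11.5 and 11.7 points (permutation test, adjusted p = 0.0052, 0.0031, 0.0026, 0.040 and 0.040). The same counts were found in both replicates' own lists, except that replicate 1's list held 19 of the 20 limb regulators. Genes of general use were also marked more often than other genes, with 24 of 24 core housekeeping genes (exact test, adjusted p = 2.0e-04) and 80 of 83 ribosomal protein genes (adjusted p = 4.7e-10); among the exceptions were Rpl10l and Rpl39l.

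Signalling genes and regulators of other organs were also marked more often than other genes. H3K4me3 was present at 41 of 43 FGF, BMP and hedgehog genes (exact test, adjusted p = 3.8e-05), the growth factor genes Fgf1 and Fgf6 being the exceptions, although replicate 1's own list held a 231 bp domain at Fgf1. It was present at 32 of 33 WNT genes (exact test, adjusted p = 1.1e-04), all but Wnt8b, at 23 of 24 neuron and placode genes (adjusted p = 0.0016), all but Neurod4, and at 19 of 20 forebrain and midbrain regulators (adjusted p = 0.0058), all but Neurod6. Of the 39 Hox genes, which set position along the body axis, 35 were marked (exact test, adjusted p = 0.0018); Hoxb3 and Hoxb8 were not, although replicate 1's own list held a domain at each. Histone genes were marked at 61 of 68 (exact test, adjusted p = 4.0e-05), surface and oral epithelium genes at 23 of 26 (adjusted p = 0.028) and imprinted genes at 18 of 20 (adjusted p = 0.040). Unmarked members included the testis histone genes Hist1h1t and Hist1h2aa, the genes Ivl and Krt1 of differentiated epidermis, and the imprinted genes Ndn and Rtl1. Lor and Krt10, other genes of differentiated epidermis picked after their values were seen, were marked.

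The chemoreceptor, hepatocyte, macrophage, germ cell and erythroid lists were marked less often than other genes. A promoter peak was found at 3 of 1463 olfactory and vomeronasal receptor genes, 1 of 20 hepatocyte genes (exact test, adjusted p = 1.2e-07), 1 of 18 macrophage and leukocyte genes (adjusted p = 5.8e-07), 3 of 20 germ cell and pluripotency genes (adjusted p = 1.2e-05) and 5 of 17 erythroid genes (adjusted p = 0.0046). The unmarked genes included Afp and Ahsg, which encode secreted liver proteins, the macrophage genes Adgre1 and Aif1, the germ cell genes Ddx4 and Dppa3, and the erythroid genes Alas2 and Gata1. The marked hepatocyte gene was Apoa1, at which neither replicate's own list held a promoter peak. Its peak in the replicated list had a fold enrichment of 22.85, and how near to the window the replicates' peaks lay was not measured. The marked macrophage gene was Spi1, with a 353 bp domain (224 and 287 bp in the replicates) at a TSS within the gene, and with the most 5' TSS alone no gene of that list was marked. The domains at Apoa1, Esrrb and Olfr94 also lay away from the most 5' TSS. Of the germ cell and pluripotency list, Klf4 and Esrrb had the widest domains, at 6105 and 2192 bp; Klf4 is also used in many somatic tissues. Receptors such as Olfr1 and Olfr10 were unmarked, and Vmn1r4 and Olfr94 were among the 3 marked ones.

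For 6 of the 26 lists no difference in share from other genes was called. Osteoblast genes were marked at 11 of 20 (exact test, adjusted p = 0.37), with Runx2, a master regulator of bone, among the marked and the osteocalcin genes Bglap and Bglap2 among the unmarked. Chondrocyte genes were marked at 17 of 20 (exact test, adjusted p = 0.11), with the cartilage regulators Sox9 and Sox6 among the marked and Col10a1, the collagen of hypertrophic cartilage, and Snorc among the unmarked. Skeletal muscle genes were marked at 20 of 28 (exact test, adjusted p = 0.72, Chrna1 and Ckm unmarked), Schwann cell and melanocyte genes at 13 of 18 (adjusted p = 0.80, Dct and Mlana unmarked), endothelial genes at 17 of 20 (adjusted p = 0.11, Emcn and Lyve1 unmarked, although replicate 1's own list held a 900 bp domain at Emcn) and cardiomyocyte genes at 9 of 18 (adjusted p = 0.24, Mybpc3 and Myh6 unmarked).

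**Figure D1:**
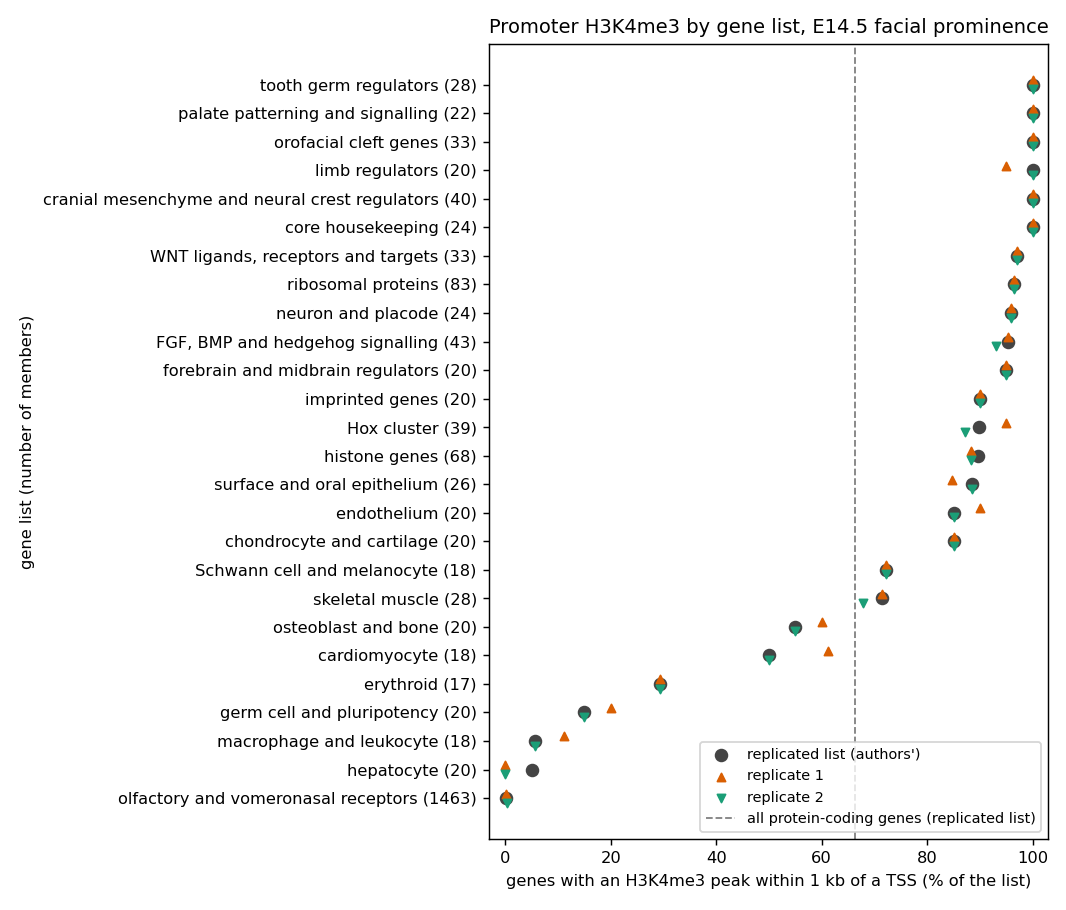
Share of genes (%) in each of the 26 gene lists with an H3K4me3 peak within 1 kb of a TSS, for the authors' replicated list (circles) and each replicate's own list (triangles); the dashed line is the 66.3% of all protein-coding genes. The cranial, cleft, tooth, palate and housekeeping lists sit at 100% in both replicates, and the macrophage, hepatocyte and chemoreceptor lists lie near the left edge.

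Against genes of like CpG content most of these differences were smaller, and some calls did not hold. Matched on the CpG ratio, the differences were 8.98 rather than 29.1 percentage points for FGF, BMP and hedgehog genes (permutation test, adjusted p = 0.049), 10.8 rather than 33.7 for housekeeping (0.049) and 17.9 rather than 23.7 for imprinted genes (0.033). For hepatocyte genes the difference was -21.0 rather than -61.4 (permutation test, adjusted p = 0.049) and for chemoreceptor genes -12.7 rather than -70.9 (0.0017). The epithelium (22.1 points against 22.2) and germ cell (-53.9 against -51.4) differences were little changed. In the same permutation test the calls of the neuron (adjusted p = 0.15), forebrain (0.12), WNT (0.20), ribosomal (0.21), Hox (1.0) and macrophage (0.19) lists were lost, the erythroid difference turned from -37.0 to 2.69 percentage points (adjusted p = 1.0), and the histone difference turned from 23.4 to -7.91 (adjusted p = 0.0017). Calls were gained in this permutation test by the skeletal muscle (5.10 to 19.8 points, adjusted p = 0.033), chondrocyte (adjusted p = 0.049) and endothelium (0.049) lists. With no call in either comparison, the osteoblast difference turned from -11.3 to 16.1 points and the cardiomyocyte difference from -16.3 to 2.78. The Hox call was also lost at the stricter threshold (exact test, adjusted p = 0.12), the imprinted call without chemoreceptors in the background (0.10) or with the most 5' TSS alone (0.19), and the epithelium call without replicate 2 (0.075) and in 5 other settings (0.072 to 0.17). The endothelium list was called marked more often without replicate 2 (23.5 points, exact test, adjusted p = 0.040) or with the pooled list (22.8 points, 0.038). The cardiomyocyte list was called marked less often with the most 5' TSS alone (-30.3 points, exact test, adjusted p = 0.020).

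H3K4me3 at facial regulators formed domains several times wider than at other genes. The 40 cranial mesenchyme and neural crest regulators had a median domain width of 8312.5 bp, against 2303.5 bp in random lists of marked genes, a ratio of 3.61 (permutation test, adjusted p = 4.0e-04, the smallest adjusted value the random lists gave). The medians in the replicates' own lists were 8463 and 8560.5 bp, so the difference was far larger than the spread between replicates (SD 68.9 bp, n = 2). Palate genes had a median of 7123.5 bp, the 11 marked osteoblast genes 6323 bp, tooth germ regulators 4831.5 bp, orofacial cleft genes 4788 bp and chondrocyte genes 4144 bp, each with permutation test, adjusted p = 4.0e-04. These lists share members with the cranial list, and without those members each remained wider than random lists, the tooth list at 3313 bp with permutation test, adjusted p = 0.0059. Against random lists matched on CpG number, chosen after seeing the data, the ratio of each of these lists was lower. It was 2.59 rather than 3.61 for the cranial list and 2.22 rather than 3.10 for palate genes. For tooth germ regulators it was 1.63 rather than 2.10 and for cleft genes 1.68 rather than 2.09. The changes were small for osteoblast (2.66 rather than 2.75) and chondrocyte genes (1.77 rather than 1.80). Each list remained wider than the matched lists (permutation test, adjusted p = 5.2e-04 for each).

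The widest domain of all lay over Trps1, a regulator of cartilage and hair follicle growth, at 23280 bp (chromosome 15, 50869140 to 50892419), but its width was 10300 bp in replicate 1 and 24300 bp in replicate 2. Nr2f2 followed with 23048 bp (23128 and 16188 bp in the replicates). Ebf3 had 20291 bp. The neighbouring homeobox genes Dlx1 and Dlx2, which pattern the jaw, shared a domain of 20062 bp (chromosome 2, 71527241 to 71547302, with 19977 and 19972 bp in the replicates). Next came Meis2 (18140 bp), Nfib (17093 bp, over a TSS within the gene), Tfap2a (17050 bp), the T-box genes Tbx3 (16736 bp) and Tbx2 (16285 bp), and Six2 (15395 bp).

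Domains at the other facial regulators named in advance ranged from 2004 to 15022 bp. Alx1, needed for the midface, had 15022 bp, and Lhx8 had 14201 bp. Twist1, a regulator of the cranial neural crest, had 14083 bp (14024 and 13795 bp in the replicates), Prrx1 had 13601 bp, Hand2 had 13177 bp and Msx1 had 12704 bp. Dlx5 had 9155 bp (9037 and 5311 bp in the replicates), Barx1 8318 bp (4586 and 12007 bp in the replicates), Shox2 7306 bp, Sox9 7156 bp and Runx2 7137 bp. The epithelial regulators Trp63 and Irf6 had 4788 bp, at a TSS within the gene, and 2004 bp. Satb2 (14079 bp) and Dlx5 were widest among osteoblast genes, Wnt5a (14763 bp) and the hedgehog receptor gene Ptch1 (14274 bp) among palate genes, and Sox6 (11466 bp) and Sox9 among chondrocyte genes.

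**Figure D2:**
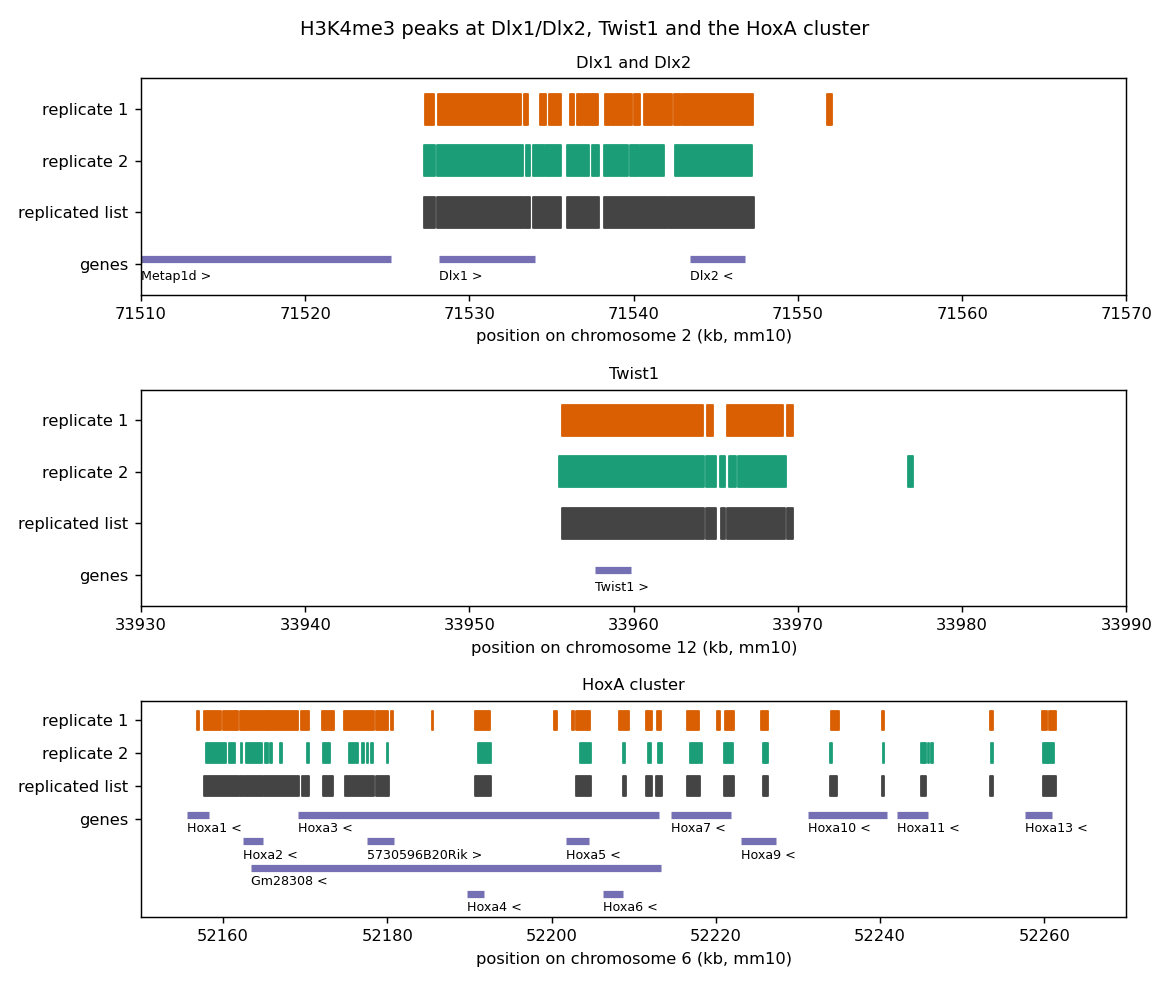
H3K4me3 peaks (bars) in replicate 1, replicate 2 and the replicated list over Dlx1 and Dlx2, Twist1 and the HoxA cluster, with genes below (arrowheads give the strand) and positions in kb on mm10. At Dlx1 and Dlx2 the replicated peaks joined into a domain of 20062 bp and at Twist1 into 14083 bp, while most HoxA genes carried separate narrow peaks and Hoxa1 and Hoxa2 shared a domain of 12808 bp.

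Wide domains were not limited to facial genes. Imprinted genes had a median of 4807.5 bp, with 12702 bp at the fetal growth factor gene Igf2 and 9955 bp at Gnas, and forebrain and midbrain regulators had 4765 bp, with 13811 bp at Six3 (6425 and 6997 bp in the replicates) and 13345 bp at Emx2 (8761 and 15247 bp). WNT genes had 4014 bp (Wnt5a and, at 11978 bp, Lef1), histone genes 3911 bp, FGF, BMP and hedgehog genes 3817 bp (Ptch1 and, at 9621 bp, Fgfr2), limb regulators 3793 bp (Meis2 and, at 14688 bp, Meis1) and ribosomal protein genes 2859.5 bp (7044 bp at Rpl35 and 5882 bp at Rps2). Each of these had permutation test adjusted p = 4.0e-04. Histone genes lie close together, and the 9999 bp domain shared by Hist1h1b and Hist1h2an was joined only in the replicated list, with 5892 and 6245 bp at Hist1h1b and 2572 and 2495 bp at Hist1h2an in the replicates. Neuron and placode genes had a median of 2931 bp (permutation test, adjusted p = 0.047), with 9496 bp at Six1 and 9090 bp at Isl1. The neuron call was lost without replicate 1 (permutation test, adjusted p = 0.18) and in 4 other settings (0.056 to 0.33), and the limb call was lost against lists matched on CpG number (adjusted p = 0.28).

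Hox genes had narrow domains, with a median of 1682 bp over the 35 marked members (ratio to random lists 0.731, permutation test, adjusted p = 0.0022; 1754 and 1308 bp in the replicates). Hoxa1 and Hoxa2 were exceptions, sharing 12808 bp (chromosome 6, 52157691 to 52170498; 13725 and 8093 bp). The Hox peaks were also weak, with a median fold enrichment of 7.77 against 54.4 for all marked genes in the replicated list, and against random lists matched on fold enrichment the Hox median was higher, not lower (ratio 1.51, permutation test, adjusted p = 0.0080). Macrophage and leukocyte genes were called narrower (permutation test, adjusted p = 0.019), which rests on Spi1 alone and was lost when matched on fold enrichment (adjusted p = 0.11). Some named genes shared their domain with a neighbour's promoter, among them Shox2, Sox6, Rps2, Rpl35, Chmp2a and Vmn1r4, and the domains at Fgfr2, Gnas and Egfl7 lay over a TSS within the gene.

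No width difference was called for the other 10 lists. Medians were 2868 bp for epithelium (permutation test, adjusted p = 0.072; 5814 bp at Esrp1), 2744.5 bp for housekeeping (0.13; 5736 bp at Chmp2a and 5113 bp at Polr2a), 2698 bp for Schwann cell and melanocyte (0.33; 6177 bp at Egr2 and 4095 bp at Pou3f1), 2192 bp for germ cell and pluripotency (0.88), 2172 bp for cardiomyocyte (0.79; 7542 bp at Gata6 and 6323 bp at Myl3, a domain shared with the osteoblast list's Pth1r), 2158 bp for endothelium (0.68; 4275 bp at Esam and 4096 bp at Egfl7), 2105.5 bp for skeletal muscle (0.49; 11982 bp at Pax3 and 11114 bp at Tbx1), 1495 bp for erythroid (0.096; 3881 bp at Tal1 and 1689 bp at Epor), 1306 bp for hepatocyte (0.29) and 1230 bp for chemoreceptor genes (0.080; 1265 and 737 bp in the replicates). Matched on fold enrichment, skeletal muscle (ratio 1.68, permutation test, adjusted p = 0.013) and endothelium (1.51, 0.041) turned from below to above random lists, and epithelium (1.88, 7.4e-04) and Schwann cell and melanocyte (1.41, 0.048) gained a call, while without joining skeletal muscle was called narrower (0.551, 4.3e-04). With joining up to 3 kb cardiomyocyte turned to above random lists (permutation test, ratio 1.96, adjusted p = 0.0067), and in 3 settings housekeeping was called wider (0.012 to 0.030) and in 2 settings chemoreceptor genes narrower (ratio 0.336 and 0.329 against 0.531, adjusted p = 0.0028 and 0.0037).

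**Figure D3:**
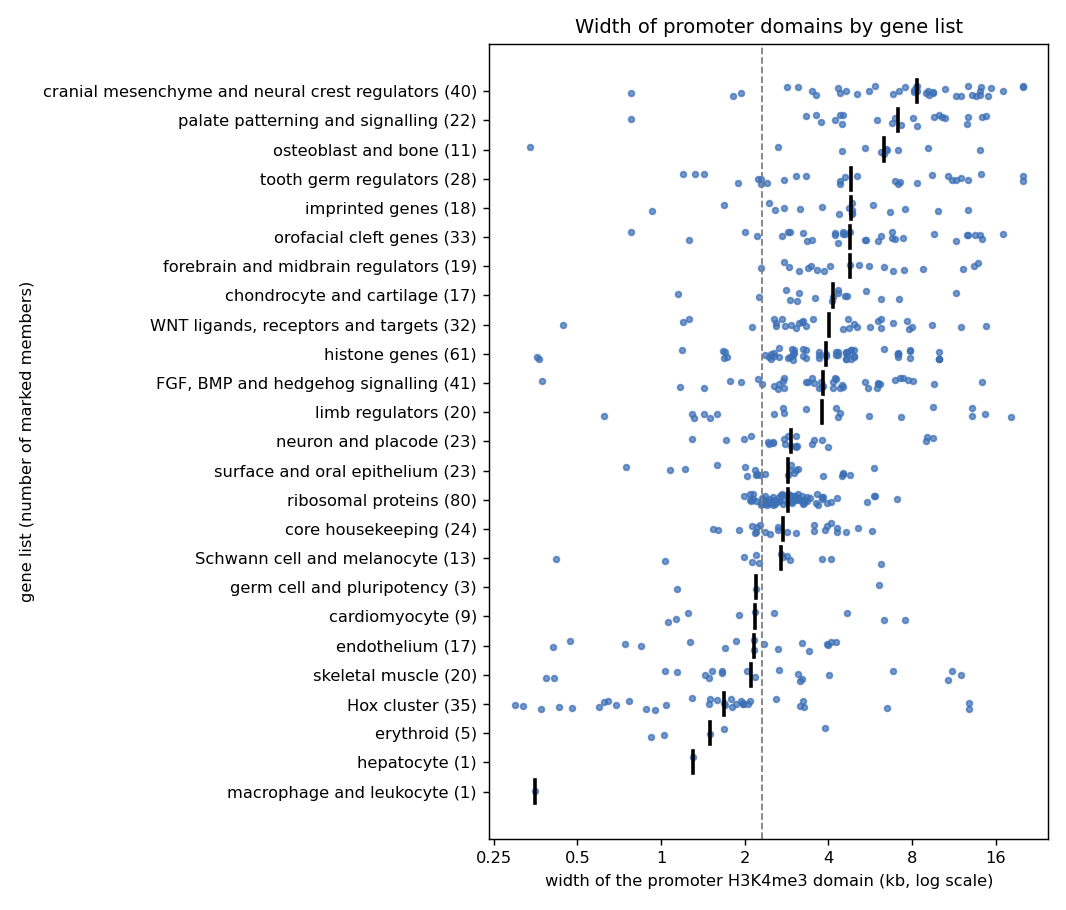
Width of the H3K4me3 domain (kb, log scale) at each marked member of a gene list (points; vertical bars are medians) in the replicated list; the dashed line is the median of all marked genes, 2301 bp, and the chemoreceptor list is not drawn. The cranial list has the highest median, 8312.5 bp, and the Hox genes lie mostly left of the dashed line.

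The replicates shared most of their peaks. Of replicate 1's peaks, 85.0% (23663 of 27830) were found in replicate 2, and 79.9% of replicate 2's (23429 of 29331) were found in replicate 1 (82.5% ± 3.64, SD, n = 2), against at most 2.46% and 2.31% in 100 random placements. Shared sequence made up 34.1 of 41.8 Mb, a Jaccard index of 0.816 against at most 0.00841 in the random placements. These placements covered whole chromosomes, while 62.4% of replicated peaks lay at promoters, which hold 2.37% of the genome. Exceeding them therefore shows only that both lists favour the same kinds of sequence, not how closely the replicates match. Across the shared peaks, which are not independent replicates, fold enrichment in the replicates had a Spearman rho of 0.851 and a Pearson r of 0.865 on the log2 scale, over 23663 pairs. The width of promoter domains had a rho of 0.925 across genes.

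Peaks in 1 list only were narrow and weak. Their median width was 256 bp in replicate 1 (4167 peaks) and 246 bp in replicate 2 (5902 peaks), against 1359 and 1404 bp for shared peaks. Their median fold enrichment was 3.40 and 3.28, against 22.8 and 26.1 for shared peaks in the same list (permutation test, p = 0.0001 for each, the smallest that 10000 resamples can give). They lay at promoters in 21.1% and 17.2% of cases, against 63.2% and 63.9% of shared peaks.

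**Figure D4:**
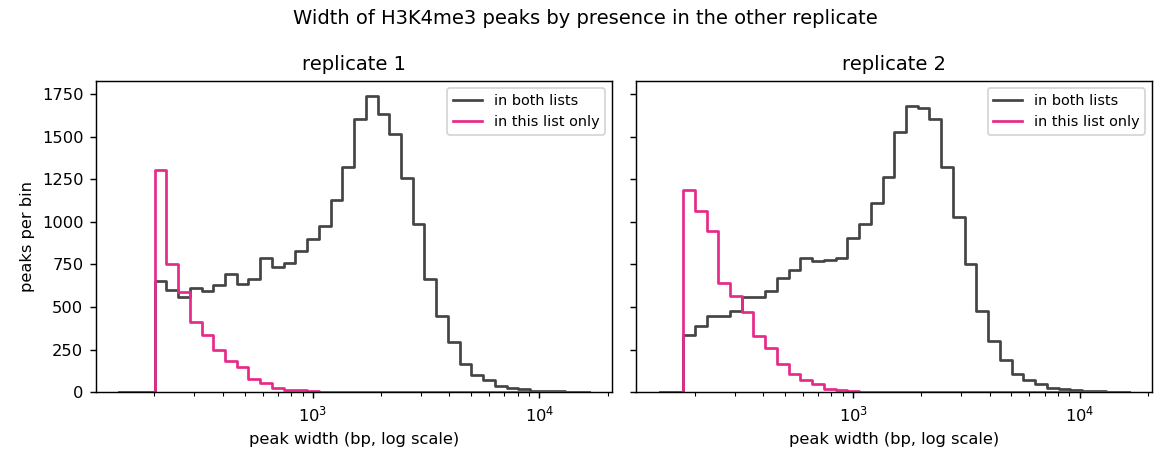
Number of peaks per width bin (bp, log scale) in each replicate's list, for peaks found in both lists (grey) and in that list only (pink). Peaks in 1 list only have medians of 256 and 246 bp, and shared peaks have medians of 1359 and 1404 bp.

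At the gene level 14397 promoters were marked in both replicates' lists, 144 in replicate 1 only and 157 in replicate 2 only. Among these, the most enriched peaks were at Tnnc1, Tchh and Nhlh2 in replicate 1 and at Gckr, Tmem253 and Apobr in replicate 2. At all 6 the other replicate also had a peak, which lay 86, 12, 11, 65, 82 and 36 bp outside the promoter window. A peak of the other replicate within 1 kb of the window was found for 28 of the 144 genes and 21 of the 157.

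Promoters held 62.4% of replicated peaks (14730) and 2.37% of the genome; exons held 11.9%, introns 11.1% and intergenic sequence 14.6%. In the replicates' own lists promoters held 56.9% and 54.5%. Of the 8882 peaks outside protein-coding promoters, 1965 (22.1%) lay within 1 kb of the TSS of another annotated transcript. Distal peaks numbered 4164 (17.6%; 17.9% ± 0.944 in the replicates' lists, SD, n = 2), of which 2547 were intergenic, 1180 in introns and 437 in exons. Their median width was 650 bp and their median fold enrichment 6.22, against 2072 bp and 50.3 for promoter peaks. The most enriched distal peaks lay in an intron with Ppara as the nearest protein-coding gene (chromosome 15, 85669600 to 85674689, fold enrichment 77.7), in intergenic sequence nearest to Fcgr4 (chromosome 1, 171037622 to 171039032, fold enrichment 77.7) and in intergenic sequence nearest to Pum2 (chromosome 12, 8640241 to 8641790, fold enrichment 69.5).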

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

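Of the tests in this part, the enrichment of Hox peaks as an explanation and the Hox comparison without Hoxa1 and Hoxa2 were chosen after their results were seen, and matching on CpG number was chosen after seeing the data; the outcome each other explanation would need was written down before its test was run. Data outside the comparisons held 10 replicated peaks on unplaced or unlocalised scaffolds, which the annotation used here does not cover. They also held 6604 pooled peaks outside the replicated list, 21.9% of the pooled list, with a median width of 246 bp, a median fold enrichment of 2.82 and −log10 q of at least 5 in 8.81%.

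For the wide domains of the cranial regulators, the values argue against joining of neighbouring peaks and against CpG-rich surroundings as the whole cause. Without joining of neighbouring peaks, the list's median was still 2.409 times that of random lists, and against lists matched on CpG number within 5 kb it was 2.587 times as high. Both ratios were below the 3.61 of the main comparison, so each may account for part of the width. They were not applied together. Wide domains at developmental regulators of any tissue would bring forebrain, midbrain and limb regulators to the same width. The cranial median was 4254 bp higher, at 8312 against 4058 bp over 37 other genes of those lists (permutation test, p = 0.0040). Those genes include the signalling genes Shh, Fgf4 and Fgf8 and the Hox genes Hoxa11, Hoxa13, Hoxd11 and Hoxd13, and Hox domains were narrow. The comparison therefore does not decide whether developmental regulators of any tissue have equally wide domains. The design held no second tissue or condition, so whether the widths are particular to the face was not tested.

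Peaks in 1 replicate's list only go with weak signal near the calling threshold: 9.023% of them in replicate 1 and 13% in replicate 2 had −log10 q of at least 5. Repeat sequence is argued against, since the median share of soft-masked bases was 9.524% and 9.362%, against 9.494% and 9.686% in shared peaks. Differences in depth between the libraries stay open, as no read counts were used, and a difference between the pools of embryos was not tested.

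For the narrow Hox domains, fewer CpG around the most 5' TSS are argued against, within the limits of the match given above. Among lists matched on CpG number, the Hox median was at percentile 0. Low enrichment of the Hox peaks could account for the narrow domains, since against lists matched on fold enrichment the Hox median was 1.509 times the random one (permutation test, unadjusted p = 0.0046). A small share of cells from the neck or hindbrain arches, which use Hox paralogues 1 to 4, may add to the pattern: these had domains 1713 bp wider than paralogues 9 to 13, at 2598 bp (n = 11) against 885 bp (n = 15; permutation test, p = 3.6e-04). The medians were 3251 and 1350 bp in replicate 1 and 1825 and 1096 bp in replicate 2. Paralogues 1 to 4 also had the higher median fold enrichment, at 13.5 against 6.23, so their wider domains do not separate this explanation from low enrichment. Without Hoxa1 and Hoxa2 the difference was 1089 bp (n = 9 against 15, exact permutation p = 0.021), and the median of paralogues 1 to 4 so reduced was 2597 bp in replicate 1 and 1720 bp in replicate 2. What lowers the enrichment, few cells with the mark or little mark in many cells, stays open.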

How the results depend on the processing

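Matching on CpG ratio or CpG number, leaving cranial members out of other lists, and the replicated list limited to peaks overlapping both replicates' lists were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because both samples belong to 1 group. No read counts were used, so the part depth plays in weak peaks was not measured. The cause was not tested for any change given here, except that distance, window and overlap rules move counts by construction.

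The share of peaks found in the other replicate (82.5%) became 93.2% at the stricter threshold, 94.7% with the top 20000 peaks and 73.4% with 50% of both peaks; the Jaccard index (0.816) became 0.847 at the stricter threshold and 0.852 with the top 20000 peaks; rho (0.851) became 0.883 at the stricter threshold, 0.823 with 1 bp overlap and 0.932 with 50% of both peaks. The width and enrichment differences between shared and single-list peaks kept their direction and threshold with 1 bp overlap.

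With the pooled list, promoters held 52.3% of peaks, 67.2% of genes were marked, the high, intermediate and low CpG classes were marked at 98.7%, 82.5% and 19.7%, and 20.6% of peaks were distal. At the stricter threshold these were 65.0%, 66.0%, 98.5%, 80.5% and 17.5% (distal share within the spread). With peaks overlapping both replicates' lists they were 65.5%, 65.9%, 98.5%, 80.3%, 17.4% and 16.4%. With 1 replicate left out they ranged from 54.5% to 56.9%, from 66.5% to 66.6%, from 98.6% to 98.6%, from 81.4% to 81.4%, from 18.4% to 18.6% and from 17.3% to 18.6%. A 2 kb promoter window gave 66.1% of peaks and 67.0% of genes, a 500 bp window 65.9% of genes and the most 5' TSS alone 63.6%. Distal peaks made up 24.8% at 2 kb and 12.4% at 10 kb.

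The numbers of lists marked more often (12 to 16), marked less often (4 to 6) and with wider domains stayed within 1.5 times of 15, 5 and 14 in all settings; lists with narrower domains went from 2 to 0 when matched on fold enrichment. Reversed, with a call in the main setting or in the alternative, were the shares, matched on CpG ratio, of erythroid (2.69 points, permutation test, adjusted p = 1.0) and histone genes (-7.91, 0.0017). So were the width ratios, matched on fold enrichment, of skeletal muscle (1.68, permutation test, adjusted p = 0.013), endothelium (1.51, 0.041) and Hox genes (1.51, 0.0080), and that of cardiomyocyte genes with joining up to 3 kb (1.96, 0.0067). Of the values of single lists, 237 shares and 239 widths stayed on their side of the threshold with no called reversal. These include values that changed direction without a call in either setting. Examples, matched on CpG ratio, are the osteoblast (-11.3 to 16.1 points) and cardiomyocyte (-16.3 to 2.78) shares. In contrast, 15 shares and 7 widths lost the call, and 6 and 8 gained one. Of the widths of named genes, 297 moved by less than the SD between replicates and 171 by more. Without replicate 2 the endothelium share gained a call (exact test, adjusted p = 0.040) and the epithelium share lost one (0.075); without replicate 1 the neuron width lost its call (0.18), and the housekeeping (0.030) and chemoreceptor (0.0037) widths gained one. The cranial list kept its wide domains in all settings, with ratios from 2.41 without joining to 5.25 with joining up to 3 kb.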

Other observations

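The counts in this part were all chosen after the data were examined. Among the 145 genes in the widest 1% of promoter domains (at least 8263 bp) were 21 of the 40 cranial mesenchyme and neural crest regulators (Fisher's exact test over the 26 lists, adjusted p = 6.5e-31). The 145 also held 10 of 28 tooth germ regulators (exact test, adjusted p = 1.1e-12), 9 of 22 palate genes (3.0e-12), 8 of 33 orofacial cleft genes (6.0e-09), 5 of 20 limb regulators (6.7e-06) and 4 of 19 forebrain and midbrain regulators (1.4e-04). Also called were 3 of 20 skeletal muscle genes (exact test, adjusted p = 0.0037), 3 of 23 neuron and placode genes (0.0049), 3 of 32 WNT genes (0.010), 2 of 11 osteoblast genes (0.012) and 2 of 18 imprinted genes (0.030). The histone list was called with 4 of 61 genes (exact test, adjusted p = 0.0093), but all 4 lie in 1 domain of 9999 bp, which was below the 8263 bp cut in both replicates' own lists. Without members of the cranial list the osteoblast (0 of 9; exact test, adjusted p = 1.0) and neuron (1 of 21; 0.32) calls were lost. The palate (6 of 17; exact test, adjusted p = 1.0e-07), tooth (5 of 21; 9.8e-06), cleft (5 of 29; 3.6e-05), limb (4 of 19; 9.0e-05), forebrain (9.0e-05), WNT (0.0091), muscle (2 of 18; 0.028) and imprinted (0.028) calls were kept. Both muscle genes, Tbx1 and Pitx2, are also tooth germ regulators. Six3 of the forebrain list was below the 8263 bp cut in both replicates' own lists (6425 and 6997 bp). Barx1 was below it in replicate 1's list (4586 bp). The counts rest on widths in the replicated list. No ribosomal protein, housekeeping, endothelial or epithelium gene was among the 145, nor any Schwann cell and melanocyte, erythroid, macrophage, hepatocyte, cardiomyocyte, germ cell or chemoreceptor gene. The widest 1% would hold few members of lists of this size by chance, so these absences do not set the lists apart.

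Annotated starts of noncoding genes carried a peak less often than those of protein-coding genes. Of 10155 lncRNA genes 2647 (26.1%) had a peak within 1 kb of a TSS, and of the 7434 lying over 5 kb from a coding TSS 763 (10.3%) did. Pseudogenes were marked at 2.63% and miRNA genes at 15.3%, and those over 5 kb from a coding TSS at 1.73% and 5.15%. The start of the annotated transcript was taken as the TSS, and whether transcription starts there was not tested, for miRNA genes in particular. Among noncoding genes picked by hand, the imprinted genes H19 and Meg3 had domains of 3753 and 3660 bp, Malat1 had 8470 bp, Neat1 5174 bp, Mir17hg 3968 bp and Xist 3722 bp, while of the lncRNA genes in Hox clusters Hotair and Hottip were unmarked and Hotairm1 lay in the 12808 bp domain of Hoxa1 and Hoxa2. By chromosome, the share of marked protein-coding genes was highest on chromosome 12 at 81.3%, 51.9% on X, and 4 of 183 genes on Y. Of the distal peaks, 766 (18.4%) had a CpG ratio of at least 0.6, against 47.2% of promoter peaks.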
